A study of Homo sapiens with 12 samples.

How the data were processed

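RNA sequencing was deposited for 12 libraries of MDA-PCa-2b, an established human prostate cancer cell line, by the sample labels; their growth protocol also names MDA-PCa-2a, a conflict that the labels leave unsettled. Per the labels they form 4 groups of 3 libraries, named NT, DHODH knock down 1 (KD1), DHODH knock down 2 (KD2) and a rescue of knock down 2 (KDR). The labels state neither what NT stands for, nor the kind of knockdown construct, nor how the rescue was made, so the groups are named here as the labels name them. Per the labels, the libraries were made from total RNA with a poly-A selection kit and sequenced as read pairs on an Illumina NovaSeq X Plus.

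The authors deposited one table per library with raw counts per gene. Per the file headers, these counts were made with featureCounts 1.6.4 over exons grouped by gene identifier, with Ensembl release 111 on GRCh38 and no option for strand, pairs or reads that map to many places. The labels also name FastQC, cutadapt and HISAT2, whose versions are not given in the sources used here. No pair option was set, so each end of a pair was counted on its own, and the share of odd values among counts of 1 to 20 was 40.2% to 46.4%. Reads that map to many places are not counted by default, so genes with near-identical copies are measured less surely than others.

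Each table held 63241 genes, of which 42338 had a symbol in the annotation used here, with 99.3% of all counts. Total counts per library ran from 23786288 to 38240369. The file of counts was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the group, which left 19373 genes, libraries were scaled by trimmed mean of M values (TMM), and 1 quasi-likelihood model was fitted to all 12 libraries with the group as its only term. A gene was called where its Benjamini-Hochberg adjusted p, over the genes tested in that comparison, was under 0.05. Counts per 1e6 counts (CPM) are scaled by TMM and are given as means with the SD over 3 libraries, and log2 fold changes carry their SE or a 95% interval from the model. P-values measure the spread between libraries, which may be technical, since the labels do not say whether the libraries of a group come from separate cultures.

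The 6 comparisons were KD1 with NT, KD2 with NT, KDR with KD2, KDR with NT, KD2 with KD1, and the mean of KD1 and KD2 with NT. Before the data were examined, 43 gene lists were fixed from knowledge of the pathways. They cover pyrimidine supply, the themes in the series title, proliferation, stress, lipids, ribosomes, prostate cell types and other cell types. The 41 lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. For each list, members called over all genes tested are given with the count adjusted over the list alone.

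Genes named in the text follow a rule that was also fixed before the data were examined. It takes DHODH, CAD and UMPS in every comparison. It takes the 8 protein-coding genes with the largest rise and the 8 with the largest fall in each comparison, among called genes with a mean of at least 5 CPM over the groups compared and no overlap between the libraries of both groups. It takes up to 4 members of each list by adjusted p, and follows the same genes into the other comparisons. Some genes that the rule or the later choice would name are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

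Alternatives planned before the data were examined were DESeq2 1.42.0, its size factors within edgeR, no filter on low counts, a minimum of 1 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, a minimum absolute log2 fold change of 1, camera with an estimated correlation, fry, and leaving out each library in turn. Offsets corrected for GC content and limma-voom with library weights were added after the data were seen. The replicate numbers do not pair the libraries: of 18 pairs of libraries from different groups with the same number, 3 had a residual correlation across genes above 0.1 (range -0.21 to 0.31).

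The method was tested on simulated data with known changes. Of genes given a 2-fold change, edgeR called 86.7% for KD1 with NT, 82.7% for KD2 with NT, 82.7% for KDR with KD2 and 86.7% for KDR with NT. For genes given a 1.5-fold change these shares were 62.7%, 77.3%, 61.3% and 69.3%. The simulation gave all groups the same spread per gene and changed only genes of at least 1 CPM. The spread between replicates was larger in NT than in the other groups, so shares for comparisons with NT may be too high. Because KD2 with NT shares libraries with KDR with NT and with KDR with KD2, groups without any change were simulated 20 times against the same libraries to give the level that sharing alone produces. No deposited library was left out.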

Results

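Expression was measured by poly-A RNA sequencing in MDA-PCa-2b, a human prostate cancer cell line, in 12 libraries of 4 groups with 3 libraries each. The groups are labelled NT, KD1, KD2 and KDR, where KD1 and KD2 are labelled as knockdowns of DHODH and KDR as the rescue of knock down 2. DHODH encodes dihydroorotate dehydrogenase, the mitochondrial enzyme of pyrimidine synthesis that passes electrons to ubiquinone. Libraries held 23786288 to 38240369 counts. The typical spread between replicates, as the biological coefficient of variation, was 15.7% in NT, 6.62% in KD1, 7.17% in KD2 and 5.53% in KDR. It was 8.56% in NT without replicate 2.

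**Figure D1:**
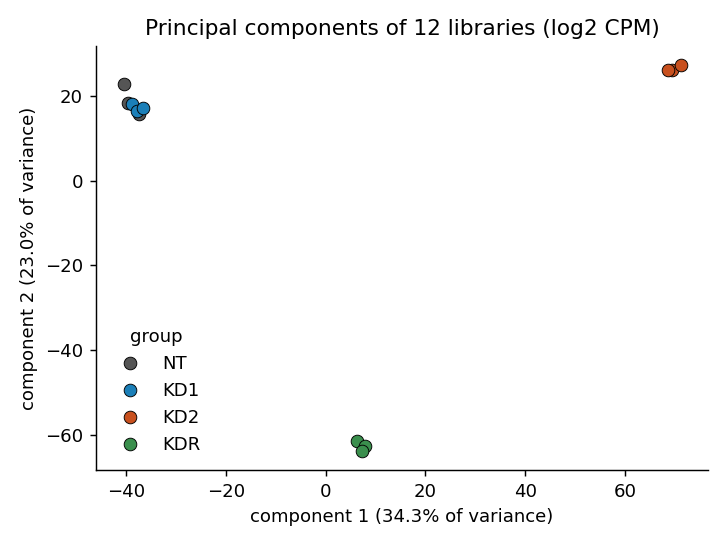
Principal components of the 12 libraries from log2 CPM, with component 1 (34.3% of the variance) on the x axis and component 2 (23.0%) on the y axis, each point being 1 library coloured by its labelled group. KD2 lies at 68.6 to 71.1 on component 1, KDR at 6.36 to 7.89, and the NT and KD1 libraries share the range from -40.5 to -36.6. On component 2 KDR lies apart from all other groups, at -63.8 to -61.5 against 15.7 to 27.2.

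DHODH RNA was not called lower in the libraries labelled KD1 or KD2 than in NT. DHODH (ENSG00000102967, GRCh38 chromosome 16, 72008588 to 72027664) stood at 10.5 ± 2.51 CPM in NT, 10.3 ± 0.674 in KD1, 13.1 ± 1.73 in KD2 and 18.6 ± 0.918 in KDR (mean ± SD, n = 3 each). Against NT, the log2 fold change was -0.03 in KD1 (95% interval -0.33 to 0.27, edgeR with Benjamini-Hochberg adjusted p = 0.97) and 0.31 in KD2 (0.02 to 0.60, adjusted p = 0.097). In KDR, the DHODH level rose by 0.51 over KD2 (0.22 to 0.79, adjusted p = 0.0064) and by 0.82 over NT (0.53 to 1.11, adjusted p = 1.0e-04). All 3 KDR libraries lay above every other library. Between 235 and 647 counts per library fell on DHODH. NT replicate 2 had the highest DHODH level of its group at 13.4 CPM; without it, KD2 exceeded NT by 0.52 (adjusted p = 0.0014), and KD1 differed from NT by 0.19 (adjusted p = 0.93). Without KD2 replicate 1, the rise in KDR over KD2 was 0.41 with an adjusted p of 0.052. Since no fall of the targeted RNA was called, every direction below belongs to the label of a group and not to a measured loss of DHODH RNA; protein was not measured.

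**Figure D2:**
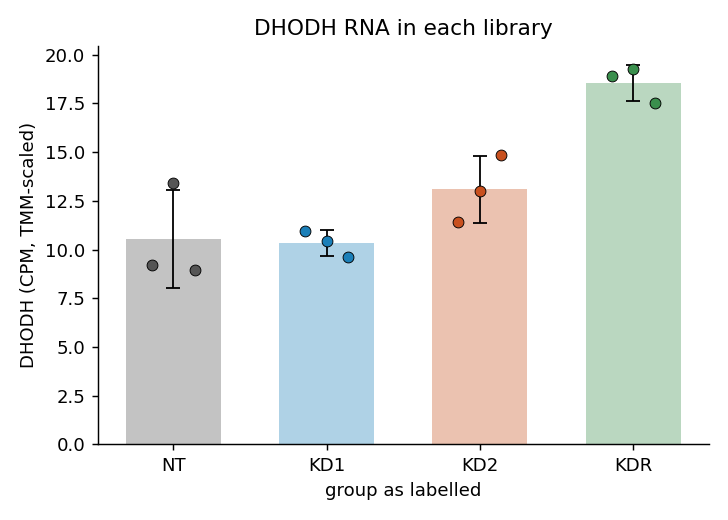
DHODH RNA in CPM scaled by TMM (y axis) in each labelled group (x axis), with bars for the mean, error bars for the SD and 1 point per library, n = 3 per group. The KD1 libraries (9.63 to 11.0 CPM) lie within the range of NT (8.95 to 13.4), and the KDR libraries (17.5 to 19.2) lie above all others.

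CAD and UMPS encode the enzymes before and after DHODH in pyrimidine synthesis. CAD (ENSG00000084774, chromosome 2, 27217369 to 27243943) stood at 126 ± 19.6 CPM in NT, 113 ± 7.31 in KD1, 162 ± 6.19 in KD2 and 126 ± 6.04 in KDR. It rose by 0.36 in KD2 against NT (0.19 to 0.53, adjusted p = 0.0011) and fell by 0.36 on the log2 scale from KD2 to KDR (adjusted p = 0.0014). UMPS (ENSG00000114491, chromosome 3, 124730433 to 124749273) stood at 26.9 ± 1.23, 25.6 ± 0.594, 31.2 ± 1.16 and 27.1 ± 1.65 CPM in the same order. Its log2 fold change in KD2 against NT was 0.22 (0.04 to 0.39, adjusted p = 0.046), a call that ended in 15 of 20 alternatives. In KDR against KD2, UMPS had a log2 fold change of -0.21 (adjusted p = 0.058).

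The comparison of the libraries labelled KD1 with NT asks what changes with the other knockdown label. The median log2 fold change was -0.0043 for mitosis genes, -0.0047 for androgen response genes and -0.04 for nuclear subunits of complex I, and no member of these lists was called. TOP2A, which untangles DNA before cell division, had a mean of 38.7 CPM in NT and 39.6 in KD1, and FOLH1, which encodes prostate-specific membrane antigen, 1491 and 1522. Of 19373 genes tested, edgeR called 0, DESeq2 0 and limma-voom 0, and edgeR without a filter on low counts called 23; the smallest adjusted p with the filter was 0.79. At an unadjusted p under 0.05 there were 1185 genes, where 969 (968.65) follow from chance. Of the 11201 genes with a mean of at least 5 CPM, 11176 (99.8%) had a 95% interval that excludes a 2-fold change in either direction, and 96.4% one that excludes 1.5-fold.

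Camera called 2 lists in KD1 against NT, neither of which held a called gene. The 13 mRNAs encoded by the mitochondrial genome had a median log2 fold change of 0.13 (adjusted p = 0.0052; adjusted p = 0.80 with an estimated correlation), with 0 members called over all genes and 0 adjusted over the list alone. MT-ND2, a subunit of complex I, had a log2 fold change of 0.21 ± 0.08 (SE, adjusted p = 0.79). In NT replicate 3 mitochondrial genes took 2.59% of the counts against 3.42% in NT replicate 1, and without that library the list had an adjusted p of 0.94. The 44 cytosolic ribosomal proteins had a median of -0.07 (adjusted p = 0.0067; adjusted p = 0.80 with an estimated correlation), again with 0 members called either way; the call ended in 6 of 21 alternatives and the direction reversed in 1, without NT replicate 2 (adjusted p = 0.89).

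The comparison of the libraries labelled KD2 with NT asks what changes with the knockdown on which the rescue was built. ATP2A3, a calcium pump of the endoplasmic reticulum (ENSG00000074370, chromosome 17, 3923870 to 3964464), rose from 8.66 ± 1.52 CPM in NT to 529 ± 23.2 in KD2 (log2 fold change 5.93, 95% interval 5.72 to 6.13). SPON2, a secreted matrix protein (ENSG00000159674, chromosome 4, 1166932 to 1208962), fell from 1038 ± 76.4 to 36.0 ± 3.72 CPM (-4.85, -4.99 to -4.72). Genes of cell division and DNA replication rose together, cholesterol and fatty acid synthesis rose, and androgen response genes and targets of the stress factor ATF4 fell. E-cadherin RNA (CDH1), which joins epithelial cells, fell from 304 to 29.8 CPM (-3.36 ± 0.08).

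In KD2 against NT edgeR called 6958 genes, 3439 higher and 3519 lower, and 1796 of them had an absolute log2 fold change of at least 1. Beside ATP2A3, the genes with the largest rises were INHBA, a subunit of activin A (0.237 ± 0.229 to 12.6 ± 0.807 CPM), the secreted protein gene REG4 (0.908 ± 0.107 to 45.9 ± 0.891), FGF12 (11.0 ± 1.10 to 372 ± 15.3), the O-glycan enzyme B3GNT6 (0.376 ± 0.160 to 11.5 ± 0.870), the adhesion receptor ADGRF5 (1.80 ± 0.344 to 53.3 ± 2.22), TMEM100 (3.77 ± 0.845 to 107 ± 3.23) and SHBG, the sex hormone-binding globulin (0.504 ± 0.194 to 11.9 ± 0.998). Beside SPON2, the genes with the largest falls were GALNT17, THNSL2, the organic cation transporter SLC22A3 (114 ± 11.5 to 1.20 ± 0.452 CPM), TMEFF2 (13.5 ± 2.10 to 0.159 ± 0.143), CEACAM20 (16.03 ± 1.95 to 0.307 ± 0.125), NLRP2 (13.3 ± 2.17 to 0.256 ± 0.0678) and the reductase gene DHRS2 (80.6 ± 8.74 to 2.85 ± 0.407). GALNT17 had 1539 counts in the NT libraries and 2 in the KD2 libraries. THNSL2 fell from 16.05 ± 1.31 to 0.0904 ± 0.0843 CPM. For each of these 16 genes all 3 KD2 libraries lay on 1 side of all 3 NT libraries, which the naming rule requires. Their adjusted p ran from 1.1e-22 for SPON2 to 1.5e-10 for INHBA.

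Proliferation and replication genes were higher in the libraries labelled KD2. Of 33 measured genes of mitosis and the G2/M phase, 32 rose and 0 fell (33 rose adjusted over the list alone), with a median log2 fold change of 1.84 (camera adjusted p = 7.1e-26; 0.0028 with an estimated correlation). TOP2A rose by 2.15 ± 0.07 (SE) and reached 171 CPM, the proliferation marker MKI67 rose by 2.20 ± 0.08 from 21.8 CPM, and CDK1, the kinase that starts mitosis, rose by 1.84 ± 0.10. Of 36 DNA replication genes, 33 rose and 0 fell (35 adjusted over the list alone; median 0.72, adjusted p = 3.4e-17), among them the licensing factors CDT1 (1.90 ± 0.09) and CDC6 (1.69 ± 0.12) and the helicase subunit MCM5 (1.16 ± 0.08).

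Lists of DNA repair genes were called for some pathways and not for others. The mismatch repair list shares PCNA, RFC2, RFC3, RFC4, RFC5 and POLD1 with the DNA replication list, and base excision repair shares FEN1 with it. The mismatch repair call is thus not separate from the rise of replication genes. Whether the other repair calls are separate from the rise of replication and mitosis genes was not tested. In homologous recombination, 17 of 28 genes rose and 0 fell (18 adjusted over the list alone; median 0.74, adjusted p = 5.4e-07), including BRCA1 (1.59 ± 0.11), the end-resection factor RBBP8 (1.49 ± 0.09) and the exonuclease EXO1 (1.92 ± 0.17). In mismatch repair 13 of 18 rose and 0 fell (14 rose and 1 fell adjusted over the list alone; median 0.36, adjusted p = 2.7e-05), with the ligase LIG1 at 0.90 ± 0.08 and the clamp loader subunit RFC3 at 0.93 ± 0.11; EXO1 is in both lists. In the Fanconi anaemia pathway 10 of 18 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.28, adjusted p = 0.00092; adjusted p = 0.072 with an estimated correlation), including FANCI (1.25 ± 0.08) and FANCD2 (1.21 ± 0.09). Base excision repair had 9 of 25 higher and 2 lower (9 and 3 adjusted over the list alone; median 0.07, adjusted p = 0.033; adjusted p = 0.22 with an estimated correlation), a call that ended in 5 of 21 alternatives, among them those without NT replicate 1 (0.055) or NT replicate 3 (0.058). Nucleotide excision repair (adjusted p = 0.78) and non-homologous end joining (adjusted p = 0.17) were not called as lists. In the former 4 of 23 genes rose and 4 fell, also adjusted over the list alone, and in the latter 5 of 16 rose and 0 fell (4 and 0 adjusted over the list alone).

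Lipid synthesis genes rose in KD2 against NT. Of 24 genes of cholesterol synthesis, 19 rose and 3 fell, the same counts adjusted over the list alone (median 0.66, adjusted p = 2.5e-07). Of 13 fatty acid synthesis genes, 9 rose and 1 fell, also adjusted over the list alone (median 0.43, adjusted p = 9.9e-05). SREBF1, a master regulator of lipid genes, rose from 122 to 467 CPM (1.94 ± 0.06), and the desaturase SCD rose from 419 to 1020 CPM (1.28 ± 0.04).

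Lists of ribosome, pyrimidine and glycolysis genes were also called up in KD2 against NT. Of 44 cytosolic ribosomal proteins, 40 rose and 0 fell (42 adjusted over the list alone; median 0.35, adjusted p = 6.8e-13; adjusted p = 0.16 with an estimated correlation), such as RPL4 (0.48 ± 0.04) and RPS13 (0.55 ± 0.05). Of 33 ribosome biogenesis genes, 20 rose and 1 fell (21 and 1 adjusted over the list alone; median 0.30, adjusted p = 3.5e-07), and MYC, which drives that programme in many cells, rose from 90.8 to 184 CPM (1.02 ± 0.06). In de novo pyrimidine synthesis 9 of 13 rose and 0 fell, also adjusted over the list alone (median 0.31, adjusted p = 0.00063). The ribonucleotide reductase subunits RRM2 (2.34 ± 0.10) and RRM1 (0.69 ± 0.07) and the enzyme DUT (0.54 ± 0.11) were among them, and DHODH itself was not. Beside CAD (0.36), UMPS (0.22) and DHODH, the list holds RRM1, RRM2, TYMS, DTYMK and DUT, so its call is not limited to the enzymes next to DHODH. Pyrimidine salvage had 6 of 15 higher and 1 lower (7 and 1 adjusted over the list alone; median 0.12, adjusted p = 0.045; adjusted p = 0.22 with an estimated correlation), with the thymidine kinase TK1 at 1.505 ± 0.106; that call ended in 15 of 21 alternatives. Of 22 glycolysis genes 11 rose and 1 fell, also adjusted over the list alone (median 0.22, adjusted p = 0.0041; adjusted p = 0.27 with an estimated correlation), and SLC16A1, a lactate and pyruvate carrier, rose by 1.76 ± 0.12.

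In KD2 against NT, lists of nuclear subunits of complexes I and IV were called down and the mitochondrially encoded mRNAs up, and none of these calls held with an estimated correlation. Of 37 nuclear subunits of complex I, 16 fell and 0 rose (23 adjusted over the list alone; median -0.25, adjusted p = 6.0e-05; adjusted p = 0.12 with an estimated correlation), for instance NDUFS8 (-0.65 ± 0.09) and NDUFB3 (-0.60 ± 0.11). Of 12 nuclear subunits of complex IV, 10 fell and 0 rose (12 adjusted over the list alone; median -0.34, adjusted p = 2.0e-04; adjusted p = 0.11 with an estimated correlation), for instance COX6C (-0.67 ± 0.07). Of 13 mitochondrially encoded mRNAs, 8 rose and 0 fell (9 adjusted over the list alone; median 0.29, adjusted p = 0.0022; adjusted p = 0.37 with an estimated correlation), for instance MT-ND6 (0.82 ± 0.05) and MT-ND1 (0.72 ± 0.08). Mitochondrial genes took 3.59% to 3.70% of the counts in KD2 and 2.59% to 3.42% in NT. In the TCA cycle 10 of 24 fell and 1 rose, also adjusted over the list alone (median -0.16, adjusted p = 0.0056; adjusted p = 0.13 with an estimated correlation); IDH1 fell by 0.70 and the citrate synthase gene CS rose by 0.45 ± 0.06. Complexes II and III (adjusted p = 0.076) and complex V (adjusted p = 0.093) were not called.

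The list of DNA and histone methylation enzymes was called up in KD2 against NT, a call that did not hold with an estimated correlation, and the methionine cycle was not called. Of 34 DNA and histone methylation enzymes and partners, 16 rose and 3 fell (19 and 3 adjusted over the list alone; median 0.21, adjusted p = 0.0020; adjusted p = 0.072 with an estimated correlation). UHRF1, which guides maintenance of DNA methylation at replication, rose by 2.19 ± 0.15, the histone methyltransferase EZH2 rose by 0.70 ± 0.09, and the demethylase KDM6A fell by 0.58. The methionine and methylation cycle was not called: 5 of 22 members rose and 6 fell, also adjusted over the list alone, and its median of 0.02 and mean of -0.19 differed in sign (adjusted p = 0.89, direction up). GNMT, which consumes S-adenosylmethionine, fell by 1.93 (SE 0.23), and MTAP of methionine salvage rose by 0.58 ± 0.08. Folate and serine one-carbon metabolism was not called either (adjusted p = 0.091, median -0.34), with 3 of 22 higher and 10 lower (4 and 10 adjusted over the list alone); ALDH1L1 fell by 5.24 (SE 0.42) and the serine synthesis enzymes PHGDH and PSAT1 fell by 0.82 and 0.86.

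Lists of ATF4, androgen response and NRF2 genes were called down in KD2 against NT. Of 31 genes of ATF4 and the integrated stress response, 28 fell and 0 rose, also adjusted over the list alone (median -0.66, adjusted p = 1.3e-15). The mitochondrial enzyme PCK2 fell from 457 to 157 CPM (-1.54 ± 0.07) and the glutathione-degrading enzyme CHAC1 from 87.4 to 29.1 (-1.59 ± 0.08). Of 29 androgen response genes, 20 fell and 4 rose (21 and 4 adjusted over the list alone; median -0.51, adjusted p = 3.5e-07). FOLH1 fell from 1491 to 290 CPM (-2.36 ± 0.04) and SLC45A3 from 2125 to 603 (-1.82 ± 0.05). Of 19 targets of the antioxidant factor NRF2, 10 fell and 1 rose, also adjusted over the list alone (median -0.27, adjusted p = 0.0065); OSGIN1 fell by 1.34 and the ferritin light chain FTL by 0.55. The unfolded protein response had 12 of 22 higher and 5 lower, also adjusted over the list alone (median 0.22), and p53 targets 12 of 27 higher and 6 lower (13 and 6 adjusted over the list alone; median 0.19); neither list was called.

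Camera called 21 of 41 lists in KD2 against NT, 15 up and 6 down, and 11 of them held with an estimated correlation. Among the fixed markers of fibroblasts, immune and endothelial cells, the highest means in KD2, beside fibronectin (FN1), were 19.3 CPM for EGFL7 (23.6 in NT), 10.1 for TAGLN (12.3 in NT), 6.44 for ESAM (10.5 in NT) and 1.96 for CD4 (0.360 in NT), and the next was ACTA2 at 1.59 (1.43 in NT). Only 3 immune and 3 endothelial markers passed the filter, too few to test. The fibroblast list was not called (adjusted p = 0.93), though FN1, which NT already expressed at 1481 CPM, rose to 3111. Lists for p53 targets (adjusted p = 0.052), the unfolded protein response (0.077), neuroendocrine markers (0.17), basal prostate markers (0.55), interferon response (0.80), ferroptosis defence (0.16), ubiquinone synthesis (0.058), mitochondrial biogenesis (0.46), mitochondrial ribosomal proteins (0.13), hypoxia targets (0.56), epithelial to mesenchymal transition (0.78), replication-dependent histones (0.97) and immediate early genes (0.29) were not called either. Each value in parentheses is an adjusted p. NT replicate 2 stood apart from the other NT libraries; without it edgeR called 7582 genes.

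**Figure D3:**
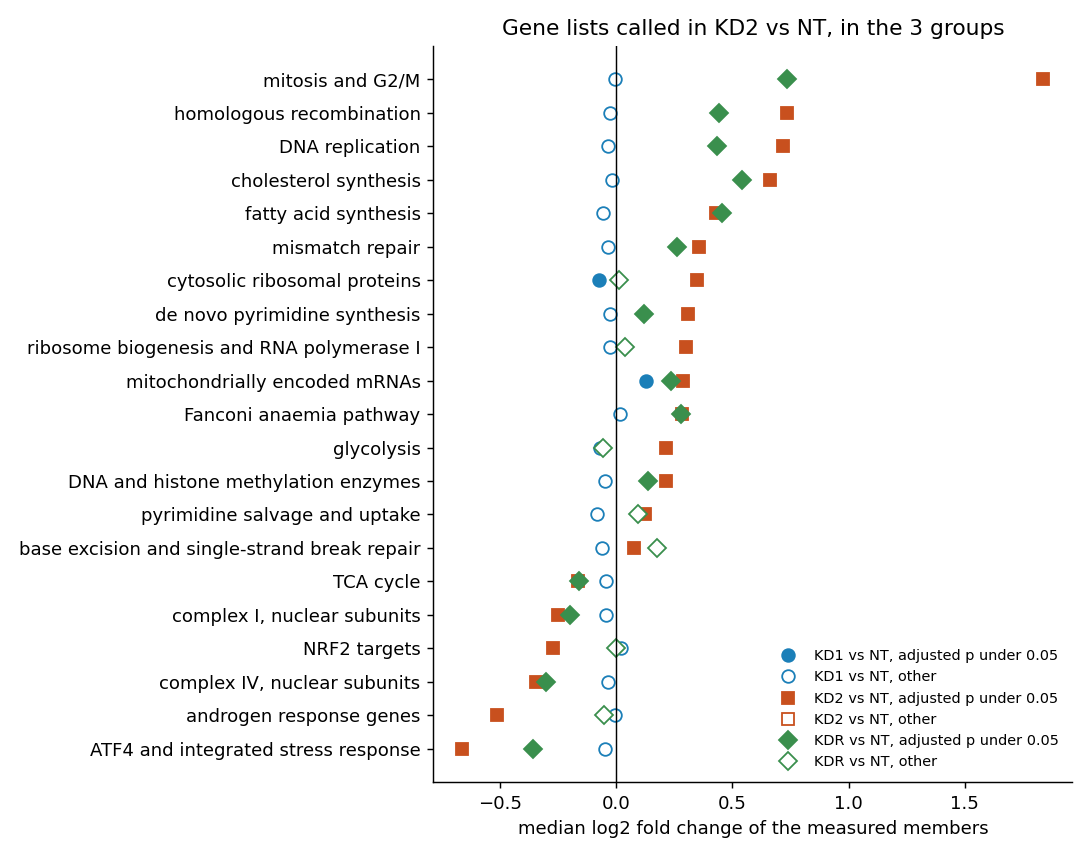
Median log2 fold change of the measured members (x axis) for the 21 gene lists called in KD2 against NT (y axis), with circles for KD1, squares for KD2 and diamonds for KDR, each against NT. Filled symbols mark a camera adjusted p under 0.05; mitosis genes stand at 1.84 in KD2 and 0.73 in KDR, and androgen response genes at -0.51 and -0.05.

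The comparison of KD2 with KD1 tests directly whether the groups labelled as knockdowns differ. The cells labelled KD2 had more ATP2A3 (5.99 on the log2 scale), CAD (0.51 ± 0.08, adjusted p = 2.8e-05) and UMPS (0.29 ± 0.08, adjusted p = 0.0085) RNA than those labelled KD1, and less SPON2 (-4.78) and SLC22A3 (-6.61). DHODH was 0.34 higher (0.04 to 0.63, adjusted p = 0.070), a difference that was called without NT replicate 2 (adjusted p = 0.018) or KD2 replicate 1 (adjusted p = 0.040). edgeR called 6868 genes, 3473 higher and 3395 lower, and camera 20 lists, of which 12 held with an estimated correlation.

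What both knockdown labels share was asked in 2 ways. With the filter on low counts no gene was called in both KD1 and KD2 against NT, since edgeR called 0 in KD1 with 1185 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Without a filter on low counts, 23 genes were called in KD1 and 9 of them also in KD2 in the same direction. The mean of both groups against NT gave 3664 genes, 1735 higher and 1929 lower, and 19 lists, of which 10 held with an estimated correlation. DHODH had a log2 fold change of 0.14 in this contrast (-0.12 to 0.40, adjusted p = 0.50), CAD of 0.11 (adjusted p = 0.33) and UMPS of 0.07 (adjusted p = 0.56). A contrast of means can be called through KD2 alone, so these calls do not show a change in both groups.

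The comparison of KDR with KD2 asks what differs between the rescue and the line it was built on, per the labels. Differences between lines or cultures cannot be told apart from the rescue here. ATP2A3 fell from 529 ± 23.2 to 5.95 ± 0.870 CPM (-6.48, -6.70 to -6.27), and SPON2 rose from 36.0 ± 3.72 to 656 ± 25.9 (4.19, 4.06 to 4.33). TRPM8, a cold-sensing channel and androgen target, rose from 4.23 to 91.1 CPM (4.42 ± 0.13). CDH1 rose from 29.8 to 254 CPM (3.09 ± 0.08). TOP2A fell from 171 to 73.3 CPM (-1.22 ± 0.07) and MKI67 to 48.0 (-1.06 ± 0.07).

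In KDR against KD2 edgeR called 6285 genes, 2972 higher and 3313 lower. By the naming rule, the largest rises were in PPFIA2, TMEFF2 (to 18.6 ± 0.968 CPM), DHRS2 (to 279 ± 8.72), CEACAM20 (to 25.2 ± 1.23), SLC22A3 (to 37.8 ± 1.21), NAALADL2 (1.86 ± 0.263 to 45.7 ± 1.40), the skin barrier gene FLG (1.16 ± 0.280 to 27.4 ± 0.564) and UGT2B28 (0.465 ± 0.193 to 10.9 ± 0.433). PPFIA2 had 3 counts in the KD2 libraries and 932 in the KDR libraries. UGT2B28 has close copies in its gene cluster, so its level is less sure. The largest falls were in ATP2A3, REG4 (to 1.02 ± 0.418 CPM), SHBG (to 0.266 ± 0.0516), ZBTB7C (33.7 ± 1.92 to 1.62 ± 0.565), INHBA (to 0.926 ± 0.152), the cancer-testis gene MAGEA4 (407 ± 5.00 to 34.6 ± 0.720), LANCL3 (82.7 ± 3.74 to 7.47 ± 0.256) and TSPAN12 (158 ± 2.99 to 15.7 ± 0.818).

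Mitosis genes fell in KDR against KD2 in 32 of 33 members, also adjusted over the list alone (median -1.06, adjusted p = 8.0e-19). DNA replication genes fell in 24 of 36 (25 adjusted over the list alone; median -0.36, adjusted p = 5.7e-07), such as MCM4 (-0.51 ± 0.06). Androgen response genes rose in 21 of 29 and fell in 4, also adjusted over the list alone (median 0.58, adjusted p = 1.1e-07). Ribosome biogenesis genes fell in 20 of 33 and rose in 1 (21 and 1 adjusted over the list alone; median -0.25, adjusted p = 2.7e-06), and genes of the unfolded protein response fell in 14 of 22 and rose in 2 (15 and 2 adjusted over the list alone; median -0.28, adjusted p = 0.0018), such as the chaperone HSPA5 (-0.62 ± 0.04). These 5 lists held with an estimated correlation, out of 17 that camera called.

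Among the 12 called lists that did not hold, integrated stress response genes rose in 25 of 31 and fell in 2, also adjusted over the list alone (median 0.35, adjusted p = 3.2e-07; adjusted p = 0.11 with an estimated correlation), with PCK2 at 1.03 ± 0.07. Cytosolic ribosomal proteins fell in 43 of 44, also adjusted over the list alone (median -0.34, adjusted p = 3.6e-13; adjusted p = 0.21 with an estimated correlation). Homologous recombination genes fell in 10 of 28 and rose in 1 (11 and 2 adjusted over the list alone; median -0.24, adjusted p = 0.0093; adjusted p = 0.21 with an estimated correlation). Interferon response genes fell in 12 of 27 and rose in 2 (12 and 3 adjusted over the list alone; median -0.52, adjusted p = 0.016; adjusted p = 0.20 with an estimated correlation): the antiviral sensor OAS3 fell by 1.84 and MX1 rose by 2.05 ± 0.08. De novo pyrimidine synthesis fell in 5 of 13 and rose in 1, DHODH (6 and 1 adjusted over the list alone; median -0.21, adjusted p = 0.032; adjusted p = 0.11 with an estimated correlation), a call that ended without KDR replicate 1 (0.053) and with a minimum of 1 CPM in 3 libraries (0.063). The other 7 called lists had adjusted p = 0.055 to adjusted p = 0.32 with an estimated correlation: p53 targets, basal prostate markers, hypoxia targets, mismatch repair, glycolysis and replication-dependent histones went down and NRF2 targets up. The call of the histones ended in 9 of 21 alternatives. The methionine cycle (adjusted p = 0.80) and the nuclear subunits of complex I (adjusted p = 0.26) and complex IV (adjusted p = 0.73) were not called.

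Of the 6958 genes called in KD2 against NT, 3716 (53.4%) were called in the opposite direction in KDR against KD2, 254 moved further in the same direction and 2988 were not called. If both sets of calls were independent, 1128 opposite calls would follow. Both comparisons use the KD2 libraries, which alone gives opposite signs: the correlation across genes was -0.60, against a median of -0.50 in simulated unchanged groups, and the covariance was -0.545 against -0.0565. The simulated groups hold no change, so any KDR line that lacks changes of KD2 would exceed their covariance. These values therefore do not show that the rescue reversed the changes. Genes are not independent replicates.

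The comparison of KDR with NT asks what differs from NT in the libraries labelled as the rescue. SREBF1 stood at 582 CPM in KDR and 122 in NT (2.26 ± 0.06), and the fatty acid synthase gene FASN at 3924 and 1969 (1.00 ± 0.06). MKI67 remained higher than in NT by 1.14 ± 0.08 and BRCA1 by 1.16 ± 0.11. FOLH1 reached 1072 CPM and SLC45A3 2112, against 1491 and 2125 in NT, while TRPM8 exceeded NT by 2.17 ± 0.10. COL2A1, a cartilage collagen, rose from 1.55 ± 0.706 CPM in NT to 53.4 ± 1.38 in KDR (5.13, 4.70 to 5.55), and stood at 4.33 ± 0.607 in KD2.

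In KDR against NT edgeR called 5337 genes, 2522 higher and 2815 lower. Beside COL2A1, the largest rises were in PPFIA2 (0.495 ± 0.0326 to 10.1 ± 1.02 CPM), SGCE (11.1 ± 2.08 to 175 ± 3.02), NAALADL2 (3.39 ± 1.43 to 45.7 ± 1.40), UGT2B28 (0.922 ± 0.0995 to 10.9 ± 0.433), the imprinted gene PEG10 (1.02 ± 0.461 to 11.1 ± 1.23), TENM1 (4.70 ± 1.19 to 43.9 ± 4.12) and UGT2B11 (1.75 ± 0.181 to 14.2 ± 0.476). The largest falls were in GALNT17 (17.4 ± 1.74 to 0.280 ± 0.188), OBSL1 (21.6 ± 2.66 to 1.41 ± 0.301), NPTX1 (13.0 ± 0.439 to 0.900 ± 0.153), the adhesion molecule NRCAM (10.6 ± 0.291 to 0.842 ± 0.475), the actin-binding protein CNN3 (23.0 ± 2.66 to 2.19 ± 0.312), SDR16C5 (12.5 ± 0.672 to 1.71 ± 0.523), THNSL2 (16.05 ± 1.31 to 2.31 ± 0.165) and NXN (14.6 ± 2.13 to 2.28 ± 0.260). UGT2B11 and UGT2B28 are near copies of each other, so their levels are less sure.

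Camera called 23 lists in KDR against NT, 11 up and 12 down, and 4 held with an estimated correlation. Mitosis genes rose in 30 of 33 members (32 adjusted over the list alone; median 0.73, adjusted p = 5.1e-15), DNA replication in 25 of 36 (30 adjusted over the list alone; median 0.43, adjusted p = 2.9e-11), cholesterol synthesis in 20 of 24 with 1 lower (21 and 1 adjusted over the list alone; median 0.54, adjusted p = 1.3e-10) and fatty acid synthesis in 10 of 13, also adjusted over the list alone (median 0.46, adjusted p = 3.3e-08). Androgen response genes were not called as a list: 9 of 29 rose and 7 fell (10 and 10 adjusted over the list alone), with a median of -0.05 and a mean of 0.09 that differ in sign (adjusted p = 0.75, direction up).

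Nuclear subunits of complex IV fell in 10 of 12, also adjusted over the list alone (median -0.30, adjusted p = 2.1e-04; adjusted p = 0.11 with an estimated correlation), for instance COX4I1 (-0.35 ± 0.06), and of complex I in 17 of 37 with 1 higher, also adjusted over the list alone (median -0.20, adjusted p = 0.0021; adjusted p = 0.18 with an estimated correlation). Integrated stress response genes fell in 24 of 31 and rose in 1 (25 and 1 adjusted over the list alone; median -0.36, adjusted p = 2.5e-09; adjusted p = 0.087 with an estimated correlation). Homologous recombination rose in 15 of 28 and fell in 1 (16 and 3 adjusted over the list alone; median 0.44, adjusted p = 2.1e-04; adjusted p = 0.10 with an estimated correlation), with BARD1 at 0.79 ± 0.09. Interferon response genes fell in 12 of 27 and rose in 2 (13 and 2 adjusted over the list alone; median -0.49, adjusted p = 0.0088; adjusted p = 0.14 with an estimated correlation), with OAS1 at -3.02 ± 0.32. Basal prostate markers fell in 6 of 11 and rose in 1, also adjusted over the list alone (median -0.56, adjusted p = 0.0031; adjusted p = 0.087 with an estimated correlation). The methionine cycle (adjusted p = 0.75) and the folate list (adjusted p = 0.52) were not called, though SHMT1, a folate enzyme, rose by 0.97 ± 0.08. Mitochondrially encoded mRNAs rose in 5 of 13 (7 adjusted over the list alone; median 0.24, adjusted p = 0.012; adjusted p = 0.46 with an estimated correlation), a call that ended without NT replicate 3 (0.22). The other 12 called lists had adjusted p = 0.087 to adjusted p = 0.30 with an estimated correlation. Mismatch repair, the Fanconi anaemia pathway, methylation enzymes, de novo pyrimidine synthesis and immediate early genes went up. Complexes II and III, complex V, the TCA cycle, ubiquinone synthesis, mitochondrial ribosomal proteins, the unfolded protein response and replication-dependent histones went down. The calls of the histones and of the unfolded protein response each ended in 5 of 21 alternatives, and that of de novo pyrimidine synthesis in 3.

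Of the 6958 genes called in KD2 against NT, 2829 (40.7%) were called in the same direction in KDR against NT, 428 in the opposite direction and 3701 were not called; 959 same-direction calls would follow if both sets were independent. A further 2080 genes were called in KDR and not in KD2, each against NT. Since these comparisons share the NT libraries, the size of the change was also compared between disjoint libraries. Across the 6868 genes called in KD2 against KD1, the change in KDR against NT was 35.7% of that in KD2 against KD1 (28.0% for genes higher in KD2 and 40.6% for genes lower), and 73.4% of the genes had the same sign. Across all genes the correlation was 0.37, against a median of 5.4e-04 in simulated unchanged groups. That simulation covers only the spread between libraries. With no gene called between NT and KD1, unrelated lines that differ from both would also give a positive correlation and a part kept. These values therefore do not show that KDR retained changes particular to KD2.

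**Figure D4:**
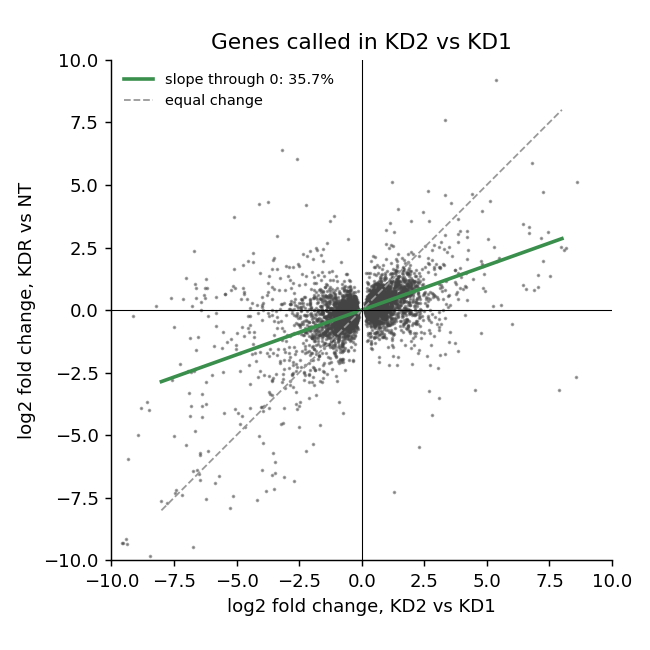
Log2 fold change in KDR against NT (y axis) and in KD2 against KD1 (x axis) of the 6868 genes called in KD2 against KD1, 1 point per gene; these comparisons share no library. The solid line through 0 has a slope of 35.7%, and the dashed line marks equal change.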

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

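The comparison of KD2 with KD1 was planned, while the tests of explanations in this part and the splits of the libraries were chosen only after the result they address was seen, except the test of NT replicate 2 against the change of KD2 and KDR.

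A difference between groups under the same contrast was found for KD1 and KD2, each against NT, by the direct test of KD2 against KD1: edgeR called 6868 genes and camera 20 lists. The log2 difference was 0.51 for CAD and 0.29 for UMPS. Among the genes with the largest rises in KD2 it was 5.99 for ATP2A3, 5.400 for INHBA, 5.26 for REG4, 4.83 for FGF12, 4.23 for B3GNT6, 4.78 for ADGRF5, 4.86 for TMEM100 and 4.77 for SHBG. Among those with the largest falls it was -9.33 for GALNT17, which had 2 counts in the KD2 libraries so that its fitted value depends on the prior count, -7.59 for THNSL2, -6.61 for SLC22A3, -6.26 for TMEFF2, -5.45 for CEACAM20, -5.55 for NLRP2, -4.78 for SPON2 and -4.76 for DHRS2. The adjusted p of these genes ran from 1.4e-22 for SPON2 to 0.0085 for UMPS. In CPM the KD2 libraries of each gene lay apart from all NT and KD1 libraries. For the genes other than CAD and UMPS the naming rule required this against NT.

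The libraries labelled KD1 had no called gene, and DHODH was not called lower in them. The lower 95% bound of its log2 fold change was -0.326, which argues against too few counts to see a fall to 1 in 2, and 0 other annotated genes overlap DHODH, which argues against reads of such a gene. Squared differences per gene between NT and KD1 libraries, over their counting variance and without NT replicate 2, had a median of 5.05 (range 3.68 to 7.05) against 3.88 to 6.99 between libraries of the same group, which is consistent with KD1 libraries from cells with the RNA of NT cells. A loss of DHODH protein without a loss of its RNA stays open, as protein was not measured. With 10 splits of the 6 libraries the splits are too few for a share under 0.05: all 10 gave as many genes as the real split, as they must with 0 in the real split, and at most 1 in another, and 6 gave as many lists, with 1 in the real split and at most 3 in another.

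Many genes were called in the libraries labelled KD2, where DHODH was not called lower. Across the autosomes and X, the largest absolute median log2 fold change was 0.0670, for genes with a mean of at least 8 CPM. This value argues against gain or loss of a whole chromosome as the whole cause. Among the complete fixed marker lists of fibroblasts, immune and endothelial cells, the highest median in KD2 was 0.205 CPM, which argues against RNA of those cells as the cause, since it would bring all their abundant transcripts; FN1, at 3111 CPM in KD2, already stood at 1481 in NT. KDR kept 35.7% of the KD2 change in libraries that share none with it. This value cannot decide on a wrong label on the KD2 libraries alone. With no gene called between NT and KD1, unrelated lines that differ from both would also share part of their change. An effect of the knockdown that is not seen in DHODH RNA may contribute, and so may differences between cultures or lines that arose during selection or growth, and no test here separates these.

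NT replicate 2 stood apart from the other NT libraries. Its deviation from them correlated with GC content across genes (Spearman 0.758, against at most 0.531 for any library of another group), so GC bias likely forms part of the cause. After GC correction the SD of the deviation fell from 0.272 to 0.177, still above the 0.102 to 0.116 of the other groups, which argues against GC bias as the whole cause. The correlation with the change of the KD2 or KDR line was at most 0.0752, which argues against RNA of those lines in it. No biological explanation was tested, since the design gives none within a group.

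For the other comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 of 10, the real split, gave the largest value each time. A mixed split of groups that differ this much adds their difference to the spread within each set. The 0 genes in such splits follow from this and are no measure of chance. Part of the difference also stays between the sets, so their list counts are no chance level either. In fits of the 6 libraries alone, KD2 against NT gave 5658 genes with at most 0 in another split, and 19 lists with at most 12. KDR against KD2 gave 7986 genes with at most 0, and 16 lists with at most 6. KDR against NT gave 4170 genes with at most 0, and 21 lists with at most 8. KD2 against KD1 gave 8080 genes with at most 0, and 22 lists with at most 12.

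For the mean of KD1 and KD2 against NT, the splits used a fit that pools KD1 and KD2, which is another form than the contrast that called 3664 genes. The real split gave 0 genes in it, a value that all 84 of 84 splits must reach, so these splits say nothing on chance for the 3664 genes; the split that sets KD2 apart gave 7343. For the lists, 32 of 84 splits of the pooled fit gave at least as many as the real split. The real split gave 16 and the highest other 21. The count followed how the KD2 libraries were divided. Splits with 1 KD2 library in the set of 3 gave 0 to 2 lists, and all others gave 14 to 21. Many splits thus carry the KD2 difference themselves, so they are no measure of chance for the lists and do not exclude it.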

How the results depend on the processing

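GC-corrected offsets and limma-voom with library weights were chosen after the data were seen; the other alternatives were planned. Over 589 results of genes other than DHODH, whose changes are given apart, and 11775 reruns, 11538 kept direction and side of the threshold, 226 lost the call, 3 gained it and 8 reversed. Apart from CAD and UMPS, these genes were taken because they were called, by fold change, by adjusted p within a list or by later choice. Their stability is thus not that of all called genes. Over 102 list calls and 2142 reruns, 2018 kept both, 123 lost the call and 1 reversed. Counts of called genes stayed within 1.5 times under each alternative except those named here. With the replicate number as a block, edgeR called 0 genes in KD1, 6882 in KD2 and 5219 in KDR against NT, 6190 in KDR against KD2, 6789 in KD2 against KD1 and 3565 for the mean of KD1 and KD2.

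Reversals concern values near 0, and their cause was not tested. The DHODH log2 fold change in KD1 against NT, -0.03, ran from -0.13 to 0.19 with 1 library left out, and was 0.02 with GC-corrected offsets (0.0233) and 0.12 with limma-voom (0.123). With 1 library left out, CAD in KDR against NT ran from -0.0722 to 0.132. The result UMPS, KDR vs NT ran from -0.0360, without NT replicate 2, to 0.0586, without KDR replicate 1, and was -0.02 (-0.0245) with limma-voom. The median of cytosolic ribosomal proteins in KD1 ran from -0.13 to -8.4e-05, where the direction of the test reversed without NT replicate 2.

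DHODH passed the threshold in KD2 against NT without NT replicate 2 (range with 1 library left out 0.21 to 0.52), with GC-corrected offsets (0.37) and with limma-voom (0.46). In KD2 against KD1 it did so in the fit of only the groups compared (0.33), with GC-corrected offsets (0.35), with limma-voom (0.34), and without NT replicate 2 or KD2 replicate 1 (range 0.24 to 0.43). In KDR against KD2 it lost the call without KD2 replicate 1 (range 0.41 to 0.60). The cause was not tested.

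With a minimum absolute log2 fold change of 1, by construction fewer genes were called: 1796 in KD2 against NT, 1683 in KDR against KD2, 1250 in KDR against NT, 1732 in KD2 against KD1 and 554 for the mean, with 807 reversed from KD2 to KDR and 490 kept in KDR. Without a filter on low counts, 23 genes were called in KD1 against NT, 9 of them also in KD2 in the same direction, and 43.5% of the 23 had the opposite sign in KDR against KD2; the other alternatives gave 0 genes in KD1, so this share had no value in them.

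Camera with an estimated correlation called 0 lists in KD1, 11 in KD2 and 4 in KDR against NT, 5 in KDR against KD2, 12 in KD2 against KD1 and 10 for the mean. Fry, which tests each list against no change and not against other genes, called 0 in KD1, 34 in KD2 and 34 in KDR against NT, 26 in KDR against KD2, 36 in KD2 against KD1 and 31 for the mean. For KD1 the count of 2 lists became 4 with DESeq2, 1 without a filter on low counts, 1 in the fit of only the groups compared, 1 with GC-corrected offsets, and 1 to 4 with 1 library left out. The cause was not tested beyond the correlation.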

Other observations

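The genes in this part were chosen after their values were seen, except FLG, MAGEA4, TSPAN12, SGCE and PEG10, which the ranking by fold change named, and the test of neighbouring genes was written before its result was seen, but its count of separate places after. Among transcription factors of prostate cells, FOXA1 rose by 0.17 in KD2 (adjusted p = 0.0023), GATA2 rose by 0.67 (adjusted p = 6.7e-10) and HOXB13 fell by 0.49 (adjusted p = 2.3e-07), each against NT. The glucocorticoid receptor gene NR3C1 fell from 50.6 ± 10.7 to 32.2 ± 1.36 CPM (adjusted p = 4.0e-05). In KDR NR3C1 stood at 36.9 ± 0.937 CPM (-0.46 against NT, 95% interval -0.68 to -0.24). FKBP5, a target of glucocorticoids and androgens, fell from 320 ± 23.1 to 151 ± 2.42 CPM. In KDR FKBP5 stood at 379 ± 7.27 CPM (0.24 against NT, 0.13 to 0.35), so these genes lay on opposite sides of NT there. The zinc carrier gene SLC30A4 fell from 1092 ± 109 to 97.9 ± 5.16 CPM in KD2 and stood at 961 ± 20.95 in KDR. The zinc-binding metallothionein MT2A stood at 55.6 ± 6.92 CPM in NT, 26.0 ± 3.37 in KD2 and 30.4 ± 1.08 in KDR. The protease gene MMP7 rose from 22.8 ± 1.72 to 428 ± 16.2 CPM in KD2 and stood at 92.8 ± 3.18 in KDR. The barrier gene HRNR fell with its neighbour FLG, from 29.5 ± 2.62 to 3.25 ± 0.734 CPM, and stood at 30.5 ± 2.04 in KDR.

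In KDR, some cancer-testis genes and an antigen presentation gene differed from NT. MAGEA4 stood at 156 ± 8.28 CPM in NT, 407 ± 5.00 in KD2 and 34.6 ± 0.720 in KDR, and MAGEA10 at 75.0 ± 9.15, 93.5 ± 3.00 and 17.7 ± 1.78. MAGEA3 stood at 130 ± 8.78, 121 ± 8.68 and 121 ± 6.24 CPM (-0.10 in KDR against NT, 95% interval -0.24 to 0.04); these genes have near copies, so their levels are less sure. HLA-DRA, which presents antigen to T cells, rose from 119 ± 12.5 in NT to 244 ± 7.79 CPM in KDR (1.03, adjusted p = 3.6e-11).

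Some changes in KD2 lay near each other along a chromosome. The order was taken over 10548 protein-coding genes with a mean of at least 1 CPM. Genes that overlap the one kept before were left out. Other genes can thus lie within a window, and that of ADCY1, IGFBP3 and TNS3 spans 45574140 to 47582558 on chromosome 7. KD2 against NT was tested in 10502 windows of 3 consecutive genes. In 9 windows all 3 genes changed by at least 1 on the log2 scale in the same direction. Over 1000 shuffles of the genes the median was 1 and the highest count 7. Windows that share genes make these 9 windows 7 separate places, against a median of 1 and at most 6 in shuffles. These counts bear on the hypothesis that changes in KD2 cluster along chromosomes, and not on its cause, which was not tested. Some of these places hold related genes, such as the metallothioneins MT2A, MT1F, MT1G and MT1X. The shuffles do not keep related genes together, so such families can raise the real count. On chromosome 7, KCND2, TSPAN12, ING3 and CPED1 all rose, ING3 from 57.3 ± 2.86 to 317 ± 18.7 CPM and CPED1 from 5.07 ± 1.07 to 65.8 ± 6.24, and in KDR they stood at 56.1 ± 3.44 and 7.41 ± 0.340. In KDR against NT, 4 windows qualified against at most 3 in shuffles, and in KD1 0. SGCE and PEG10, adjacent imprinted genes on chromosome 7, both rose in KDR.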
